A study of Homo sapiens with 3 samples.

How the data were processed

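Expression was measured in immortalized human endometrial cells with Illumina HumanHT-12 v4 bead arrays, which carry 47315 probes read in 1 colour. Per the labels, stable lines with either of 2 constructs or a non-target control were grown in medium with 10% serum, RNA was taken after 48 h with a column kit, and 1 array was run for each of the 3 lines. The groups were taken from the sample titles.

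The authors deposited an intensity per probe and array on a linear scale, together with a detection p-value for each. Per the submitters' processing notes GenomeStudio was used, without a version, and the steps run in it are not given in the sources used here. The table is named as not normalized, yet its values show earlier processing. Between 25.6% and 25.8% of the intensities are below 0, so background had been subtracted. The sorted log2 intensities of the 20000 brightest probes differ by at most 0.0592 between arrays, so the distributions had been made nearly alike. The detection p-values deposited by the authors run in steps of 1/770, the spacing given by 770 negative control beads. The authors also deposited a table of ratios, which equals each array's intensity over that of NT for 100% of probes within a relative tolerance of 1e-04. Its medians are 1 for NT, 0.942 for shRNA1 and 0.938 for shRNA2, and it holds values below 0 where 1 of the 2 intensities in a ratio is negative. It is linear and uncentred.

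Probes were named from the platform table given for these arrays. Of the probes, 30111 have 1 gene, 8 have several and 17196 are not listed. For 30072 of those with 1 gene, the symbol was updated through the Entrez ID in a RefSeq gene table of assembly GRCh38.p14, used for names only. The files name no genome build, so no coordinates are given. A gene was represented by its brightest probe. Of 20044 genes with a probe, 11674 were detected (detection p-value under 0.01) on at least 1 array and 10820 on all 3. These detection limits and the number of arrays set the precision. The lowest detected signals were 15.1, 13.9 and 15.1 in NT, shRNA1 and shRNA2.

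Intensities were processed in R 4.3.3 with limma 3.58.1. The neqc method inferred the background from the detection p-values, added an offset of 16, and normalised the arrays by quantiles. Compared with median centring of the same background-corrected values, this second normalization moved no log2 ratio of a probe detected on all arrays by over 0.0597. The median log2 ratio of all detected genes was -0.02 for both constructs. The offset pulls the ratios of dim probes toward 0, and earlier background subtraction can do the opposite in the deposited ratios. Further steps used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots used matplotlib 3.10.9.

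With the constructs as separate groups there is 1 array per group and no test was made. A limma fit that takes both constructs as 1 group against NT, with 1 residual degree of freedom, was run as an alternative. Counts are of genes at least 2-fold from NT in each direction, and "higher" and "lower" describe these arrays. As a measure of the spread between probes of 1 gene, 3016 genes had a pair of detected probes. Their log2 ratios to NT correlated across genes at 0.780 in shRNA1 and 0.822 in shRNA2, with SDs of 0.192 and 0.206 between probes. The probes of a pair share culture, RNA and array, so this spread leaves out variation between those. Both constructs share the NT array, which makes their ratios agree by itself. Counts and the correlation were therefore set beside 1000 simulations of unchanged groups, and beside the values with each construct's array as the reference. A gene undetected in 1 group has a fold given as a limit, against the higher of its own value and the lowest detected level of that array.

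Before the data were examined, 36 gene lists and the naming rule were fixed. A list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these arrays. It was called when the percentile was at least 97.5, or at most 2.5, in both constructs. Older symbols were matched for 31 members. Named genes were STK11 and CCL2, the 12 genes in each direction with the largest smaller ratio of both constructs among those detected on all arrays, up to 4 genes per direction detected on 1 side only, the 4 with the largest opposite ratios, and members of the lists, 3 per called list and up to 2 per other list. Genes outside this rule are marked as chosen after their values were seen, or stand as examples within a list.

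The counting was tested on simulated data in which 200 of 11674 genes were changed. It recovered 90% of genes changed by 1.5 log2 and 100% of those changed by 2, and counted 83 unchanged genes. No list was called on simulated unchanged data. On the real arrays 7 and 8 lists were called with shRNA1 or shRNA2 as the reference, so that result does not carry over. Alternatives were another background correction, none, an offset of 50, median centring, the deposited ratios, other detection filters, the mean of a gene's probes, a 1.5-fold threshold, and a limma fit with the constructs as 1 group. Alternatives added after the data were examined left out interferon and MHC class I genes or interferon-inducible chemokines. The 17204 probes without a single gene name were kept out of the gene counts.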

Results

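The series asked how the transcriptome of immortalized human endometrial cells depends on LKB1, a serine/threonine kinase encoded by STK11 that activates AMPK and related kinases. Stable lines carried 1 of 2 non-overlapping short hairpin RNA constructs, named shRNA1 and shRNA2 here, or a non-target control hairpin (NT). Total RNA was taken from dividing cells after 48 h in medium with 10% serum and hybridised to whole-genome bead arrays with 47315 probes. Each of the 3 lines was measured on 1 array, so no difference of a single construct from NT has a replicate check or a p-value, and the number of arrays limits the precision of each value. The NT, shRNA1 and shRNA2 arrays detected 19240, 19540 and 19227 probes. Across the 18281 probes detected on all 3 arrays, Pearson correlations of log2 intensity between arrays were 0.991, 0.988 and 0.989. Genes detected on at least 1 array numbered 11674.

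STK11 transcript was lower than in NT with both constructs. Its single probe had signals of 109.6 in NT, 31.5 in shRNA1 and 28.9 in shRNA2. The normalised log2 ratios to NT were -1.39 and -1.47, or 2.63-fold and 2.78-fold lower, on a scale whose offset compresses the ratios of dim probes. The authors' deposited table gives ratios of 0.287 and 0.263, which correspond to 71.3% and 73.7% less signal. Of the genes for its partners in the active kinase complex, STRADB had log2 ratios of 0.22 and 0.20, CAB39 0.11 and 0.07, and STRADA -0.04 and 0.08.

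Comparing each construct with NT asked which transcripts differ in cells with less STK11. CCL2, a chemokine that attracts monocytes, was 9.57-fold higher than in NT with shRNA1 and 14.8-fold higher with shRNA2. By the smaller of its log2 ratios it led all genes detected on the 3 arrays. The chemokine CXCL6 was 2.96-fold and 6.21-fold higher, and MMP12, the macrophage elastase, was 2.81-fold and 7.03-fold higher. FST (follistatin, which binds activin) was 4.72-fold and 3.58-fold higher, SFRP1 (a secreted Wnt antagonist) 4.79-fold and 2.97-fold, POSTN (periostin) 3.18-fold and 4.03-fold, and TFPI2 (a serine protease inhibitor) 4.62-fold and 2.88-fold. The NT signal of TFPI2 was 16.1, close to the lowest detected signal of 15.1, so its fold depends on the background and offset. Enzymes in this set were KYNU, of tryptophan breakdown, at 3.97-fold and 4.94-fold, and DHRS3, a retinaldehyde reductase, at 2.93-fold and 3.47-fold. PAGE5 of a cancer-testis antigen family was 5.33-fold and 6.49-fold higher, the kinesin heavy chain KIF5C 5.11-fold and 4.09-fold, and the Golgi protein gene GASK1B 3.18-fold and 3.11-fold. Second detected probes of PAGE5, KYNU, FST, POSTN, GASK1B, CXCL6 and MMP12 lay on the same side of NT with both constructs. Some genes were detected with both constructs and not in NT, so only a lower limit of the fold can be given. ALDH1A1, a retinaldehyde dehydrogenase, was at least 4.51-fold and 2.49-fold higher on its brightest probe, while its second probe, detected on 2 of the 3 arrays and so partly at background, gave fitted log2 ratios of 1.63 and 0.77, and the metallothionein MT1F at least 3.26-fold and 2.70-fold.

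Of the genes lower than in NT with both constructs, MXRA5, a matrix-associated protein gene, was 5.34-fold lower with shRNA1 and 2.88-fold lower with shRNA2. PODXL (podocalyxin, a surface sialomucin) was 3.63-fold and 2.05-fold lower, with second-probe log2 ratios of -1.23 and -0.89. CRIP2, a LIM-domain protein gene, was 3.10-fold and 2.97-fold lower, and APCDD1L 2.65-fold and 3.89-fold lower. The forkhead factor gene FOXQ1 was 2.13-fold and 2.04-fold lower, and ABCC3, an efflux transporter, 1.94-fold and 2.60-fold lower. MEDAG was 2.56-fold and 2.47-fold lower, IGSF3 2.40-fold and 2.28-fold, with second-probe log2 ratios of -0.73 and -0.47 on a probe detected on 1 array, FRMD3 2.11-fold and 2.64-fold, and EPDR1 1.88-fold and 2.19-fold. ANKRD35 was 2.31-fold and 1.91-fold lower on its brightest probe, but its other detected probe gave log2 ratios of 0.01 and -0.12. CRYAB, a small heat shock protein gene detected in NT alone, was at least 2.36-fold and 2.28-fold lower.

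**Figure D1:**
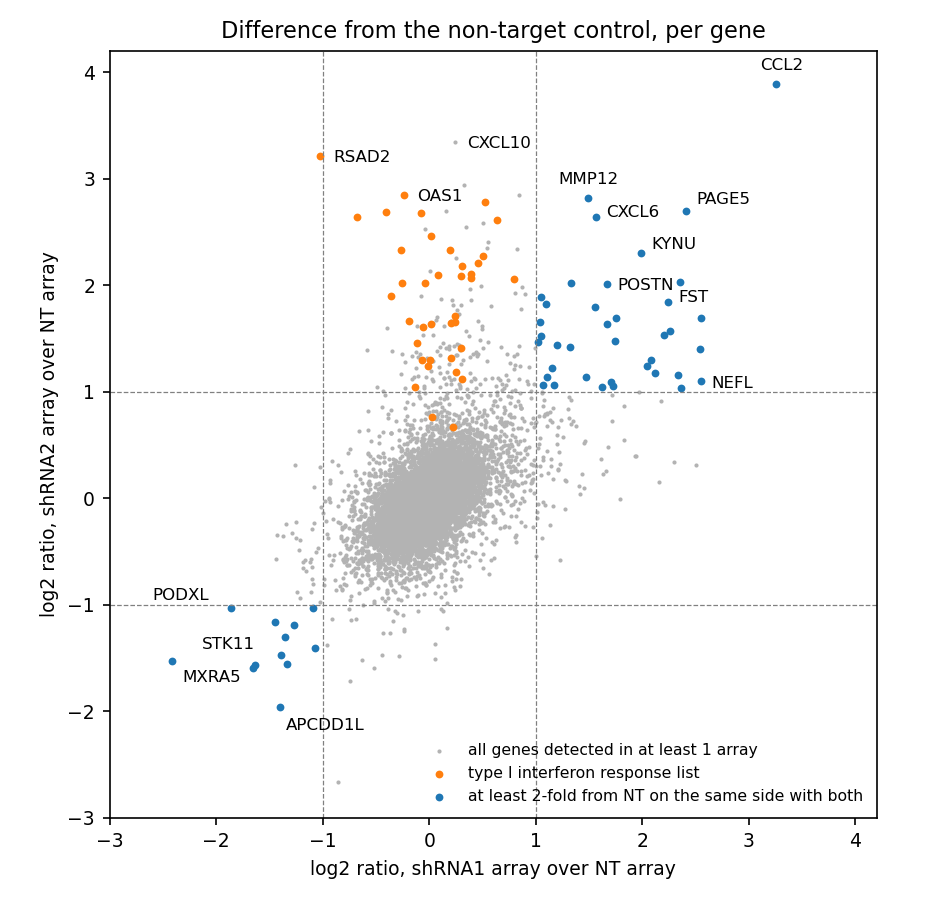
Log2 ratio to the NT array of the 11674 detected genes, shRNA1 on the horizontal axis and shRNA2 on the vertical axis, 1 array per line, with dashed lines at 2-fold. CCL2 lies farthest out on the diagonal at 3.26 and 3.88, STK11 lies at -1.39 and -1.47, and the interferon genes (orange) spread along the shRNA2 axis.

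In shRNA1, 117 genes were at least 2-fold higher than in NT and 44 were at least 2-fold lower. In shRNA2 the counts were 217 and 39. Both constructs shared 38 genes on the higher side and 12 on the lower side, and 1 gene, RSAD2, passed 2-fold in opposite directions. With undetected values raised to the lowest detected level of their array, the shared counts were 33 and 12. They were 20 and 3 with an offset of 50 in place of 16, and 120 and 33 with neither background correction nor an offset, and the simulations used the main processing alone. Independent sets of these sizes would share 2.17 and 0.147 genes, a calculation that leaves out the shared NT array. In 1000 simulations of unchanged lines against 1 shared control, with differences drawn from shRNA1 minus shRNA2, 65.6 genes on average (40 to 94) reached 2-fold on the same side, against 50 observed. By direction the simulated means were 32.7 higher and 32.9 lower, against 38 and 12 observed. With the interferon and MHC class I genes left out of those differences, a choice made after the data were examined, the mean was 42.4, made of 21.1 higher and 21.3 lower. With the smaller differences between pairs of probes of 1 gene it was 2.19, a value that leaves out variation between cultures, RNA and arrays. A gene as far out as CCL2 appeared in 10, 0 and 0 of 1000 simulations of these 3 kinds. The other named genes stood out less. In the same order, the gene farthest out had a median smaller log2 ratio of 2.80, 2.06 and 1.18, against 2.41 for PAGE5. Genes at least 3-fold from NT with both constructs averaged 11.5, 4.18 and 0, against 10 observed. With other arrays as the reference, 41 genes set the shRNA1 array and 129 genes the shRNA2 array at least 2-fold apart from both others. Across the 10820 genes detected on all arrays, the ratios of the constructs had Pearson r = 0.507 and Spearman rho = 0.504, with genes not being independent replicates. The simulation of unchanged lines gave 0.50 and 0.47. With shRNA1 or shRNA2 as the reference the Pearson values were 0.371 and 0.612. The covariance was 0.0520, against 0.0552 simulated and 0.0482 simulated without the interferon and MHC class I genes. The shared total was thus below the simulated mean with a common control and line-to-line differences of the size seen between the constructs. It lay above the mean, within the range of 21 to 64, once those genes were left out. The simulated means were nearly equal in both directions, so these simulations cannot decide what an uneven split means. The 38 higher lay above the simulated mean of 32.7 and below the simulated highest of 51, and the 12 lower lay below the mean of 32.9. The other arrays had uneven splits too. Against both other lines, 33 genes were higher and 8 lower in shRNA1, and 119 were higher and 10 lower in shRNA2.

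Of 36 gene lists fixed before the data were examined, 4 were called higher and 3 lower than in NT with both constructs, from their percentile among matched random lists. With shRNA1 or shRNA2 as the reference in place of NT, 7 and 8 lists were called, so the number alone does not set the NT comparison apart. Inflammatory chemokines and cytokines had median log2 ratios of 0.48 and 1.10 over 21 measured genes, and 17 of them were above NT with both constructs. With undetected values at their limit the medians were 0.48 and 0.79. IL6 was 2.51-fold and 4.05-fold higher and IL1B 2.78-fold and 2.19-fold higher. CXCL8, already abundant in NT, was 1.56-fold and 1.70-fold higher. CXCL12 went the other way, with log2 ratios of -1.44 and -0.57. NF-kappaB target genes had medians of 0.43 and 0.31 over 17 genes, and 14 were above NT with both constructs. TNFAIP3, a feedback inhibitor of the pathway, was 2.03-fold and 2.76-fold higher. NFKB2 had log2 ratios of 0.73 and 0.71, and TRAF1 0.58 and 0.84.

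Replication-dependent histone genes had medians of 0.75 and 0.39, and 12 of 13 were above NT with both constructs. H2AC18 had log2 ratios of 0.86 and 0.84, H4C8 0.84 and 0.91, and H4C14 0.75 and 0.78. Probes for histones, as for the PAGE, SPANX, HLA and CXCL5 and CXCL6 families, may bind transcripts of near-identical relatives, so the member is uncertain. Decidual stromal markers had medians of 0.35 and 0.71, but only 6 of 18 were measured. The leading members were the transcription factor gene CEBPD at 0.62 and 1.05, DIO2, a thyroid hormone deiodinase, at 0.41 and 0.999, and the cytokine gene IL15 at 0.30 and 0.61. The decidual call was lost when gene values were the mean of their probes, and with no filter on detection.

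Lower with both constructs were the ATF4 targets of the amino acid response, at medians of -0.29 and -0.15. Of 30 genes, 18 were below NT in both and 4 above it in both, among them ATF3 with log2 ratios of 0.46 and 1.35. DDIT4, an inhibitor of mTORC1 signalling, had ratios of -0.81 and -0.75, the amino acid transporter gene SLC7A5 -0.79 and -0.70, and VLDLR -0.60 and -0.86. The serine synthesis genes PHGDH and PSAT1 had ratios of -0.66 and -0.49, and of -0.90 and -0.58. Mitotic cell cycle genes had medians of -0.14 and -0.26, and 26 of 35 were below NT in both, none of them by 1.5-fold in both. NUF2 had ratios of -0.59 and -0.54 on its brightest probe and -0.20 and -0.30 on its second, FOXM1 -0.41 and -0.53, and CENPF -0.71 and -0.39. NRF2 targets had medians of -0.25 and -0.14, with 12 of 17 below NT in both. By at least 1.5-fold in both, 1 of the 17 was lower and 1 was higher. TXNRD1 had ratios of -0.77 and -0.63, GCLM -0.35 and -0.33, and NQO1 -0.66 and -0.32, while AKR1C3, also on this list, was higher at 0.55 and 1.46. The NRF2 call was lost in 3 alternative settings and the ATF4 call in 1.

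**Figure D2:**
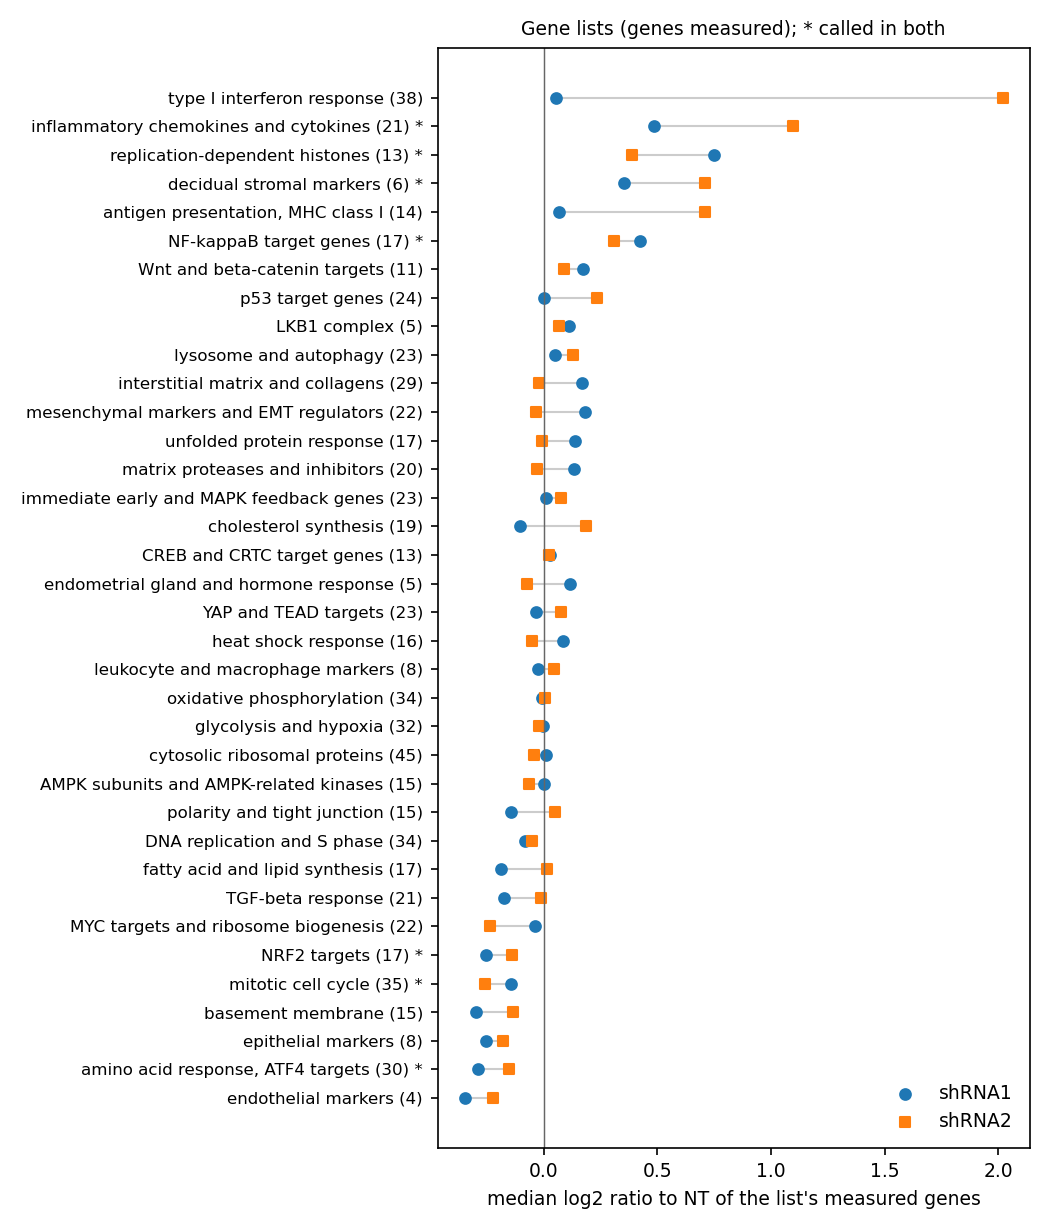
Median log2 ratio to NT of the measured genes of each of the 36 lists, for shRNA1 (circles) and shRNA2 (squares), with the number of genes measured in parentheses and an asterisk where the list was called with both constructs. The type I interferon list has the widest gap, 0.05 against 2.02.

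The other 29 lists were not called with both constructs. AMPK subunits and related kinases had medians of 0.00 and -0.07, and CREB and CRTC targets, which LKB1 signalling restrains through salt-inducible kinases, had medians of 0.03 and 0.02. Glycolysis and hypoxia genes (-0.00 and -0.02), oxidative phosphorylation genes (-0.01 and 0.01) and cytosolic ribosomal protein genes (0.01 and -0.04) stood close to NT. Basement membrane genes had medians of -0.30 and -0.13. LAMA1 had ratios of -0.81 and -0.58 and COL18A1 -0.62 and -0.59, and the list fell short of a call in shRNA2 at percentile 4.63. Cholesterol synthesis genes had a median of -0.11 in shRNA1 and 0.19 in shRNA2, TGF-beta response genes -0.17 and -0.01, and p53 targets 0.00 and 0.23. Interstitial matrix genes had medians of 0.17 and -0.02 and mesenchymal markers 0.18 and -0.03. Of 32 epithelial markers 8 were measured, with medians of -0.25 and -0.18, and leukocyte and macrophage markers had medians of -0.02 and 0.05 over 8 measured genes.

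Comparing the constructs with each other measured how far lines made against 1 target differ. Type I interferon response genes were higher in shRNA2 than in both other lines. Of 38 measured, 36 were at least 2-fold higher than NT in shRNA2 and 0 were in shRNA1, with medians of 2.02 and 0.05. ISG15 was 4.28-fold higher than NT in shRNA2 and 1.06-fold in shRNA1. The antiviral gene OAS1 was 7.21-fold higher in shRNA2 and had a log2 ratio of -0.23 in shRNA1. RSAD2, also antiviral, was 9.29-fold higher in shRNA2 and 2.03-fold lower in shRNA1. MHC class I antigen presentation genes had medians of 0.71 in shRNA2 and 0.07 in shRNA1. HLA-B had log2 ratios of 1.26 and 0.19 in that order, and TAP1 1.20 and 0.02. Further genes, chosen after their values were seen, were CXCL10, 10.1-fold higher in shRNA2 and 1.18-fold in shRNA1, and IFNB1, the gene of interferon beta. IFNB1 was detected in shRNA2 alone, at a signal of 83.7, at least 3.22-fold above NT. The interferon list stood at percentile 97.2 in shRNA1, just below the limit for a call, and passed it in 3 alternative settings. The chemokine list moved in the same direction between the constructs, with a median of 0.69 log2 more in shRNA2.

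Between the constructs, 68 genes were at least 2-fold higher in shRNA1 and 154 in shRNA2. Of the 119 genes at least 2-fold higher in shRNA2 than in both other lines, 34 were on the interferon list. Genes that stood apart in shRNA1, chosen after their values were seen, included CEMIP, a hyaluronan-degrading protein gene, 5.68-fold above NT in shRNA1 and 1.24-fold in shRNA2. SERPING1, the C1 inhibitor gene, was 4.90-fold and 1.26-fold above NT, where its signal of 15.5 was close to the lowest detected signal of 15.1. ID2, a BMP and TGF-beta target, had ratios of -1.29 in shRNA1 and -0.33 in shRNA2. Genes lower in shRNA2 than in both other lines, also chosen after their values were seen, included PTGS1, the cyclooxygenase-1 gene, with ratios of -0.85 in shRNA1 and -2.66 in shRNA2, and TERT with 0.16 and -1.22.

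**Figure D3:**
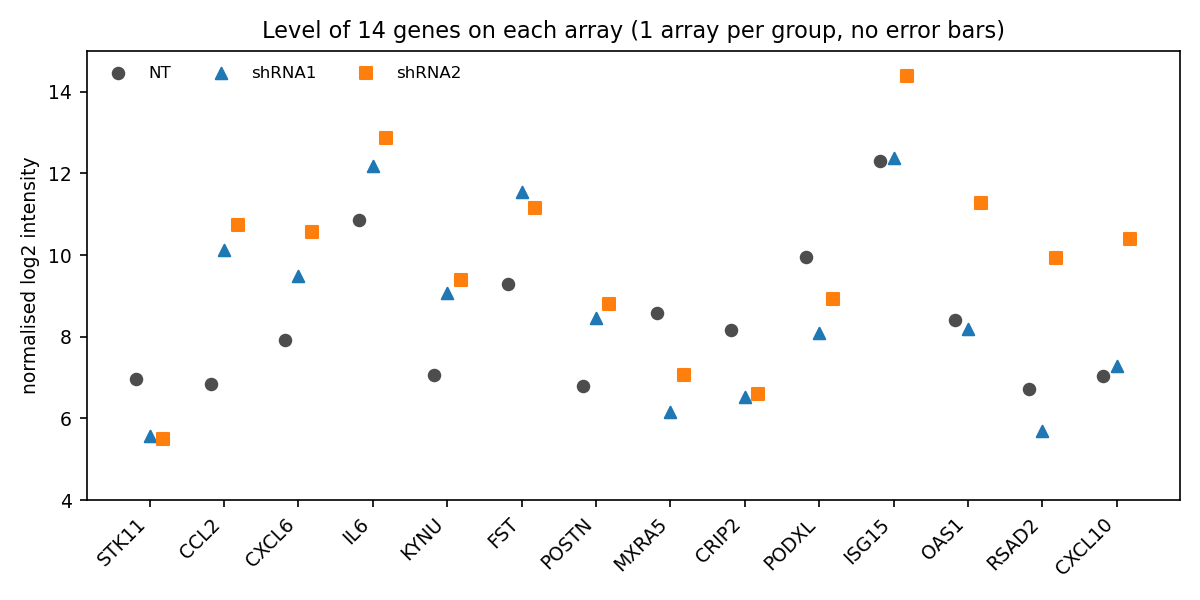
Normalised log2 intensity of 14 genes on the NT (circles), shRNA1 (triangles) and shRNA2 (squares) arrays, 1 array per line and so no error bars. CCL2 stands at 6.85, 10.11 and 10.74, STK11 at 6.96, 5.57 and 5.49, and ISG15 at 12.30, 12.37 and 14.39.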

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

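All tests of explanations in this part were chosen after the results were seen. With 1 array per line, no difference between the constructs was tested.

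The 4 genes with the largest opposite log2 ratios to NT lay above NT with 1 construct and below it with the other. RSAD2 had -1.02 in shRNA1 and 3.21 in shRNA2, CMPK2 -0.68 (undetected in shRNA1, so at least 1.59-fold lower) and 2.64, KCNH1 -0.66 and 0.63, and CXCL5 -0.59 and 1.39. The second detected probe of CXCL5 gave -0.61 and 1.18, while the other probes of KCNH1 were detected on none of the 3 arrays. Among the 4528 detected probes without a single gene name, which no comparison used, 14 were at least 2-fold higher and 2 at least 2-fold lower than in NT with both constructs, shares of 0.309% and 0.0442% against 0.326% and 0.103% of the named genes.

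Interferon response genes were higher with shRNA2 than with shRNA1, by a median of 1.73 log2. Normalization or background correction in the re-analysis is argued against, since the median difference stayed between 1.66 and 1.78 in 6 other settings. All of them start from the deposited intensities, so the steps run before deposit were not tested. Leukocyte RNA is argued against too: 17 of 24 leukocyte markers with a probe were undetected in shRNA2, including PTPRC, TYROBP, LAPTM5, FCER1G and LYZ, while the 7 detected, led by CD68 at 9.96 log2 (9.59 in NT), were detected in NT as well except CD74. A deeper STK11 knockdown with shRNA2 stays open, because STK11 differed by 0.0785 log2 on 1 dim probe and protein was not analysed here. An innate response to the shRNA2 hairpin, or to the state of that 1 culture, may also be involved and was not tested.

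Genes at least 2-fold from NT on the same side with both constructs numbered 50. Errors of single probes are argued against for the 15 genes that have a second detected probe, since 16 of 16 such probes lay on the same side of NT with both constructs, 13 of them by at least 1.5-fold in both; the other 35 genes have no such probe. Differences as large as those between the construct lines, with a shared control, could account for the total, since simulations of that kind averaged 65.6 genes and 979 of 1000 reached 50. These differences include the interferon genes of shRNA2, and without them and the MHC class I genes 135 of 1000 simulations reached 50. An NT line that stands apart for reasons of its own cannot be told apart from an effect of STK11 knockdown, since there is 1 NT array, and the shRNA2 array stood apart from both others at 129 genes.

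Inflammatory chemokines and cytokines were higher than in NT with both constructs. The interferon-inducible chemokines CXCL10, CXCL11 and CCL5 alone are argued against, since without them the 18 genes left had medians of 0.57 and 0.89, and both percentiles stayed at the top. Whether the genes left, CCL2 among them, also respond to interferon was not tested. Leukocytes in both cultures are argued against, since 16 of 24 markers were undetected in shRNA1, PTPRC, TYROBP, LAPTM5, FCER1G and LYZ among them in both lines, although CD74, undetected in NT, was detected with both constructs at 5.51 and 6.52 log2 and CD79A in shRNA1 alone at 5.01. An NT culture low in these transcripts cannot be told apart from knockdown with 1 NT array, and the constructs themselves differed by a median of 0.54 on these genes, close to the smaller shift of 0.57 from NT. A response to lower STK11, which the design names, stays among the open explanations.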

How the results depend on the processing

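All values here come from alternatives planned before the data were examined, except those that leave out genes of chosen lists. No result reversed: of 322 values for 54 named genes under the alternatives (means of both constructs), 212 moved by less than the SD between the constructs and 110 by more, with the sign kept wherever both constructs lay on the same side of NT. Counts moved with the fold threshold, and counts and the STK11 ratio with settings that change the offset, alone or together with the background correction, since an offset shrinks the ratios of dim probes. With an offset of 50 in neqc, the genes at least 2-fold higher and lower with both constructs numbered 20 and 3, those in shRNA1 58 and 14, those in shRNA2 136 and 17, and those higher in shRNA1 than in shRNA2 27; STK11 stood at -0.96 and -1.01. With normexp and an offset of 50 the shared counts were 19 and 3, shRNA1 51 and 14, shRNA2 131 and 14, between constructs 23 higher and 97 lower in shRNA1, and STK11 -0.88 and -0.92. With neither background correction nor an offset they were 120 and 33, 253 and 123, 360 and 124, 182 and 268, and STK11 -1.79 and -1.91. With the deposited ratios they were 120 and 33, 251 and 126, 361 and 121, 176 and 263, and STK11 -1.80 and -1.93. At 1.5-fold they were 164 and 77, 386 and 251, 518 and 288, and 318 and 415. With both constructs as 1 group against NT, limma with 1 residual degree of freedom called 0 genes higher and 0 lower after Benjamini-Hochberg adjustment. CCL2, with a mean log2 ratio of 3.57, was among the genes not called. With 1 NT array and 1 residual degree of freedom the fit cannot decide which genes differ, so its 0 calls do not show an absence of differences. On simulated data the same fit recovered 100% of genes changed by 3 log2. That recovery does not carry over to these arrays, where CCL2 was not called. Among genes detected on all 3 arrays the shared counts were 28 and 9. Leaving out interferon and MHC class I genes, chosen after the data were examined, gave 38 and 12 shared genes, 177 genes higher in shRNA2 and 117 lower in shRNA1 than in shRNA2. The 7 called lists kept their calls in 57 of 63 alternatives; the NRF2 call was lost in 3, the decidual call in 2 and the ATF4 call in 1. Of all 36 lists, 10 calls were gained in single alternatives, 3 each of them for the interferon and basement membrane lists. No paired analysis was possible because each group has 1 array and the labels link no arrays across groups, and no replicate could be left out. Signal over background limits the dim genes: 158 genes were detected with both constructs and not in NT, and 122 in NT alone.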

Other observations

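The matrix protease list was not called, with medians of 0.13 in shRNA1 and -0.03 in shRNA2. The collagenase gene MMP1 had log2 ratios to NT of 1.32 and 0.76, and MMP3 had 0.55 and 2.40. Fibronectin (FN1) had 0.94 and 0.48, while ZEB1, a regulator of epithelial-mesenchymal transition, had -0.63 and -0.72. Among BMP and TGF-beta feedback genes SMAD6 had -0.98 and -0.75. CDKN1A, the p21 gene, had 0.64 and 1.13, against medians of 0.00 and 0.23 for all p53 targets. The AMPK-related kinase gene NUAK2 had 0.66 and 0.72.

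MYC targets and ribosome biogenesis genes had medians of -0.04 in shRNA1 and -0.23 in shRNA2, and DNA replication genes -0.08 and -0.05. Fatty acid and lipid synthesis genes had -0.18 and 0.02, lysosome and autophagy genes 0.05 and 0.13, and the LKB1 complex 0.11 and 0.07. The unfolded protein response list had 0.14 and -0.01, the heat shock list 0.09 and -0.05, and YAP and TEAD targets -0.03 and 0.08. Polarity and tight junction genes had -0.14 and 0.05, immediate early genes 0.01 and 0.08, and Wnt targets 0.17 and 0.09. Of the endothelial markers 4 were measured (-0.35 and -0.22), and of the endometrial gland and hormone response genes 5 (0.12 and -0.07).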
